A study of Mus musculus with 10 samples.

How the data were processed

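CD4+ T cells were taken from the spleens of DBA/1 mice, naive or injected with immature dendritic cells. Per the labels' protocols, CD4+ cells were purified by negative selection with magnetic beads (Dynabeads), stained for CD4, CD49b and CD25 and sorted on a FACSAria, and cells of several mice were pooled. RNA was isolated with an RNeasy Micro kit, and 100 ng was labelled with the GeneAtlas 3' IVT Express kit and hybridised to Affymetrix mouse arrays. The deposited log2 values of 45141 probe sets on 10 arrays were made by the authors with GCRMA and Affymetrix Expression Console 1.2.1, per the submitters' processing notes, which give no order or settings. GCRMA corrects background, normalizes between arrays and summarises probes into log2 values. Whether the 10 arrays were normalized together is not given in the sources used here, so that a difference in level between groups can come partly from this step. For arrays, their number limits the precision, and no depth applies.

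The arrays fell into 4 groups by their labels: CD4+ cells of naive mice (n = 2), CD4+ cells of injected mice (n = 2), CD49b+ cells (n = 3) and CD25+ cells (n = 3), the last 2 groups from injected mice. The 4 comparisons were CD4+ of injected against naive mice, CD49b+ against CD4+ and CD25+ against CD4+ of injected mice, and CD49b+ against CD25+. Replicate numbers come from the labels.

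After 104 control probe sets were set aside, 29449 of the other 45037 were listed in the annotation of the array used here. Of these, 28898 had 1 gene symbol and 551 several, and 15588 had none here. Of those with 1 symbol, 28689 were matched by gene number to the current gene table, which changed 0 symbols. The 17097 genes were each represented by the probe set with the highest mean over all arrays, and 7180 had over 1 probe set. Of the called genes named by the rule below that had other probe sets, 10 of 15, 9 of 40, 7 of 35 and 14 of 41 in the 4 comparisons had no other probe set called the same way when adjusted over all probe sets. Genes were tested where at least 2 arrays lay above the 50th percentile of their array, which left 11037 and set aside 6060 as dim. Of the 7693 probe sets tested without a single gene name, 0 were higher and 23 lower in CD4+ cells of injected than of naive mice, 1084 and 2823 in CD49b+ and 836 and 1812 in CD25+ against CD4+ cells, and 485 and 692 in CD49b+ against CD25+ cells.

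A single limma fit (lmFit and eBayes, limma 3.58.1 in R 4.3.3) of the 4 group means, with 6 residual degrees of freedom, gave log2 differences, standard errors and p-values. All groups share 1 estimate of the spread. P-values were adjusted within each comparison by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The tests are two-sided. Genes named in the text were set by a rule. The first part takes the 10 highest and 10 lowest fold changes among called genes whose arrays did not overlap between the groups, passing over gene models. The second takes Itga2, Il2ra, Foxp3, Cd4, Il10, Ctla4 and Lag3 in each comparison. The third takes up to 4 called members of each gene list with the greatest change. Cd3e was added as a sort marker.

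The 28 gene lists, with 436 symbols of which 374 had a probe set and 303 were tested, cover sort markers, the regulatory T cell signature, type 1 regulatory T cell genes, suppressive effector molecules, coinhibitory receptors, naive and quiescent T cell genes, effector and memory T cell genes, T helper 1, T helper 2, T helper 17 and T follicular helper genes, chemokine receptors, integrins, T cell receptor activation targets, immediate early and stress genes, cell cycle, interferon-stimulated, glycolysis and cholesterol synthesis genes. The others hold markers of cells that the sort could hold: natural killer cells, natural killer T cells, CD8 T cells, gamma-delta T cells, B cells, myeloid and dendritic cells, neutrophils and basophils, platelets and megakaryocytes, and erythroid cells. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. No list call held with an estimated correlation in any of the 4 comparisons. That correlation was estimated from only 6 residual degrees of freedom. The fry test was a further alternative, which asks whether the members of a list changed, while camera sets them against the other genes. The lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined.

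The alternatives were no filter on dim genes or a stricter one (70th percentile), quantile normalization or median centring of the deposited values, another eBayes prior, the mean of the probe sets of a gene or every probe set, a 2-fold threshold, array weights, the replicate number as a block, only the arrays of the groups compared, other CD4+ comparators, and each array left out in turn. Where that left 1 array in a group, it was assumed to vary like the other groups. Both replicate 3 arrays of the subsets left out, the poly-A signal as a covariate and the crossed pairing were chosen after seeing the data. Same-numbered CD49b+ and CD25+ arrays deviated together, with correlations of deviations from the group means of 0.158, 0.366 and 0.641, so that the numbers were taken to pair these arrays, from the data.

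The procedure was tested on simulated data with 200 changed genes of the 11037. Between the CD4+ groups it recovered 42.3% of genes changed by 0.5 on the log2 scale and 85.2% of those changed by 1. In CD49b+ against CD4+ cells it recovered 47.9% and 90.5%, in CD25+ against CD4+ 49.9% and 88.4%, and in CD49b+ against CD25+ 56.3% and 92.6%. False genes among the calls came to 5.1%, 5.17%, 4.68% and 4.62% in the same order. For the lists, simulated in CD49b+ against CD25+ cells, camera called 0.06 of 26 lists on average with no effect. The glycolysis list, the only one moved, by 1, was called in 100% of 50 simulations. Genes varied independently there, while in the data the estimated correlation reached 0.734 for the cell cycle genes. These simulations therefore cannot show how often camera calls the real lists falsely.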

Results

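Gene expression was measured in CD4+ T cells from the spleen of DBA/1 mice, an inbred strain, on 10 Affymetrix mouse expression arrays. Of these, 2 arrays held CD4+ cells of naive mice and 2 held CD4+ cells of mice injected with immature dendritic cells, antigen-presenting cells that have not been activated. The other 6 held subsets sorted from injected mice. CD4+ cells carrying CD49b, the integrin alpha 2 chain encoded by Itga2, were on 3 arrays, and CD4+ cells carrying CD25, the interleukin 2 receptor alpha chain encoded by Il2ra, on 3. Injected mice had received 500000 immature dendritic cells into the peritoneum 7, 5 and 3 days before the spleens were taken. Cells of several mice were pooled for each sort, and the labels do not say that the replicates of a group came from separate pools. The p-values therefore measure the spread between these samples, which may be technical. The deposited values are log2 expression values, so that a difference of 1 is a 2-fold difference. The number of arrays limits the precision: the median standard error (SE) of a log2 difference over the 11037 genes tested lay between 0.099 and 0.121 in the 4 comparisons.

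The CD49b+, CD25+ and CD4+ arrays lay apart on the first 2 principal components. The CD4+ arrays of naive and of injected mice overlapped there, with naive replicate 1 at -33.62 and injected replicate 2 at -33.61 on the first. The first principal component took 59.4% of the variance and placed the 4 arrays of CD4+ cells opposite the 3 of CD49b+ cells, with the CD25+ cells between. The second took 23.5% and placed the CD25+ cells apart from all others. Array medians were 4.79 and 4.80 in the arrays of CD4+ cells of naive mice, 4.80 and 4.81 in those of injected mice, and between 4.61 and 4.65 in the 6 arrays of the subsets. The median of the 23 nonspecific control probe sets, which measure background, averaged 3.38 and 3.39 in the CD4+ groups, 3.27 in CD49b+ and 3.21 in CD25+ cells. The signal of the poly-A transcripts added before labelling averaged 8.66 and 8.51 in replicate 3 of CD49b+ and of CD25+ cells, and between 5.52 and 6.98 in the other 8 arrays. The difference between the 3' and 5' probe sets of Gapdh, a sign of RNA quality, averaged 0.02 ± 0.05 (SD, n = 2) in CD4+ cells of naive mice and 0.19 ± 0.09 (SD, n = 2) in those of injected mice. It was 0.46 ± 0.23 (SD, n = 3) in CD49b+ and 0.52 ± 0.12 (SD, n = 3) in CD25+ cells. That of Actb did not follow the same order, at 0.46 ± 0.05 and 0.53 ± 0.04 (SD, n = 2) in the CD4+ groups, 0.50 ± 0.06 (SD, n = 3) in CD49b+ and 0.64 ± 0.02 (SD, n = 3) in CD25+ cells. Where the lower of 2 groups lay under the median of its arrays, the gene may be near background there, and its fold change is then a lower bound with no firm rank.

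**Figure D1:**
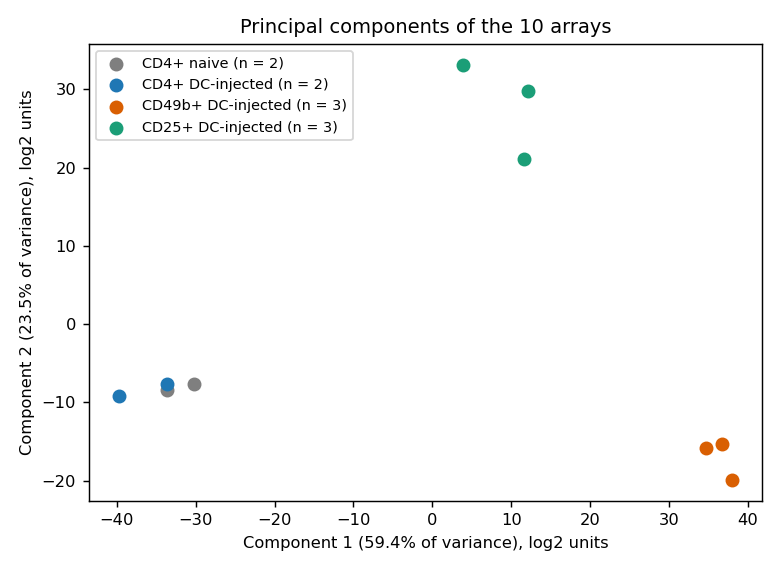
Each point is 1 array, placed by its first (x axis) and second (y axis) principal component over the 11037 genes tested, in log2 units, and coloured by group. The 3 CD49b+ arrays lie between 34.8 and 38.0 on the first component, the 3 CD25+ arrays between 3.88 and 12.2, and the 4 CD4+ arrays between -39.7 and -30.3.

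The transcripts of the sort markers were examined first. Il2ra stood at a mean log2 level of 4.17 in CD4+ cells of naive and of injected mice, 6.29 in CD49b+ and 8.83 in CD25+ cells. It was higher in CD25+ than in CD4+ cells of injected mice (4.66 ± 0.14, adjusted p = 1.97e-07), and also higher in CD49b+ than in CD4+ cells (2.12 ± 0.14, adjusted p = 3.12e-06). Between the CD4+ groups it differed by 0.00 ± 0.16, adjusted p = 1. Itga2 stood at 5.72 and 5.82 in the CD4+ groups, 5.78 in CD49b+ and 5.47 in CD25+ cells, and the CD49b+ cells were not called different from CD4+ cells (-0.05 ± 0.11, adjusted p = 0.717). The difference of Itga2 between CD49b+ and CD25+ cells was 0.31 ± 0.10, adjusted p = 0.0349, and that between CD25+ and CD4+ cells -0.36 ± 0.11, adjusted p = 0.0247. The first of these Itga2 calls was lost without CD49b+ replicate 2 (0.21, adjusted p = 0.108) or 3 (0.0789), or CD25+ replicate 1 (0.09) or 3 (0.0877). The second was lost without CD4+ replicate 1 (0.078) or 2 (-0.33, adjusted p = 0.118), or CD25+ replicate 1 (0.0539) or 3 (0.0604). The differences of Cd3e, a chain of the T cell receptor complex, were 0.00 ± 0.13, adjusted p = 1 between the CD4+ groups, 0.16 ± 0.12 in CD49b+ and -0.02 ± 0.12 in CD25+ against CD4+ cells, and 0.18 ± 0.11 between the subsets. None of them was called. Cd4 differed by -0.17 ± 0.11, adjusted p = 0.622 between the CD4+ groups and by 0.04 ± 0.10, adjusted p = 0.778 in CD25+ against CD4+ cells, where another probe set of Cd4 was called lower (-0.45, adjusted p = 0.0028). It was called higher in CD49b+ than in CD4+ cells (0.34 ± 0.10, adjusted p = 0.0184) and than in CD25+ cells (0.30 ± 0.09, adjusted p = 0.0326). The former call was lost without CD4+ replicate 1 (adjusted p = 0.0762) or 2 (0.075) or CD49b+ replicate 1 (0.0564). It was also lost with the arrays centred on their medians (0.15, adjusted p = 0.162) and with the mean of the probe sets of Cd4 (0.14, adjusted p = 0.19), and another probe set of Cd4 gave -0.06. The latter was lost without CD49b+ replicate 1 (adjusted p = 0.107) or 3 (0.0528), or CD25+ replicate 1 (0.0543) or 3 (0.0987). Of the 4 sort markers, 0 were called between the CD4+ groups, 2 were higher in CD49b+ and 1 was higher and 1 lower in CD25+ against CD4+ cells, with the same counts adjusted over the list alone. Between CD49b+ and CD25+ cells 2 were higher and 1 lower, also over the list alone, with a median of 0.24 and a mean of -0.44. The median and mean also differed in sign between the CD4+ groups.

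**Figure D2:**
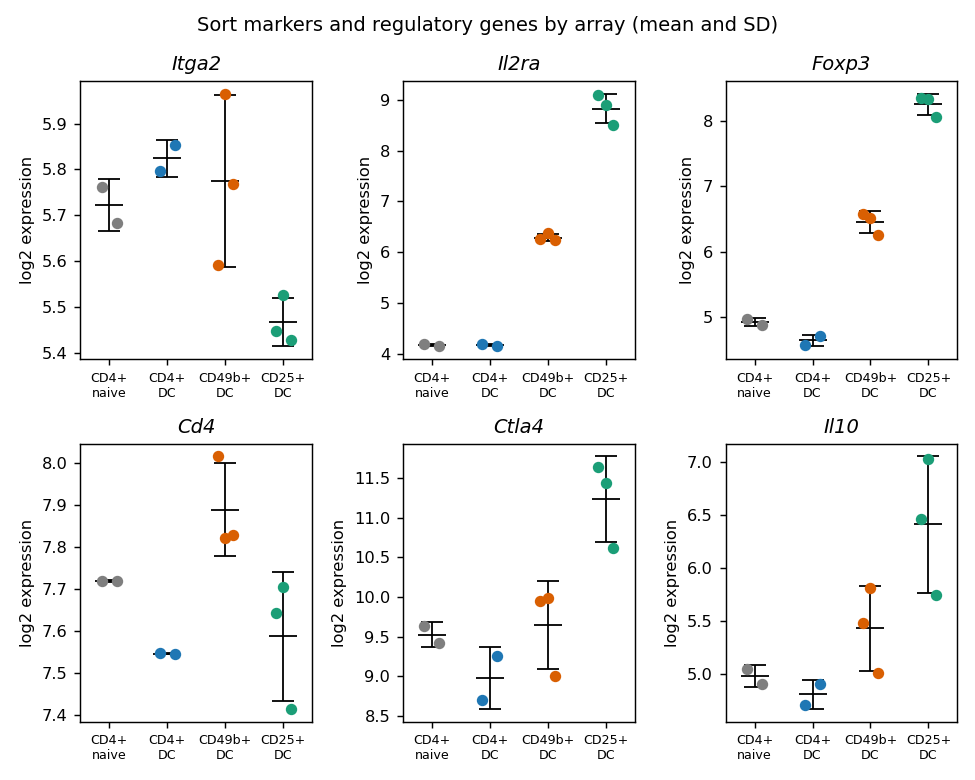
Log2 expression (y axis) of 6 genes in each array (points) of the 4 groups (x axis), with the group mean and SD (bars). Il2ra and Foxp3 stand highest in the 3 CD25+ arrays, with means of 8.83 and 8.25, and lower in the 3 CD49b+ arrays, with means of 6.29 and 6.45.

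The first comparison set CD4+ cells of injected mice against those of naive mice, which the labels name as the profile of dendritic cell vaccination. In cells of injected mice 4 of 10 genes of follicular helper T cells, which help B cells in germinal centres, were called lower, as were 4 of 9 B cell markers and 5 of 18 myeloid and dendritic cell markers. None of these list calls held with an estimated correlation (adjusted p = 0.0701, 0.109 and 0.0701), and 0 genes were called in limma when the 4 arrays were fitted alone. With fry, which asks only whether members changed, the adjusted p were 0.00284, 0.00711 and 0.00284. Cxcr5, the chemokine receptor that leads cells into B cell follicles, was -1.82 ± 0.23 on the log2 scale (SE, n = 2 and 2; adjusted p = 0.00587), a 3.54-fold lower level. Pdcd1, which encodes the inhibitory receptor PD-1, was -1.76 ± 0.16, adjusted p = 0.00228, and H2-Aa, a chain of MHC class II, -1.7 ± 0.31, adjusted p = 0.0314. The call of H2-Aa was lost without any 1 of the 4 arrays (adjusted p from 0.0746 to 0.321), and that of Cxcr5 without naive replicate 2 (0.0783). The lowest gene was Fscn1, which encodes the actin-bundling protein fascin (-2.28 ± 0.30, adjusted p = 0.00721). Its call was lost without naive replicate 2 (adjusted p = 0.0783) or injected replicate 1 (0.0554). The other 3 probe sets of Fscn1, one of them about as bright, gave -0.05, -0.04 and 0.03, and none was called. In the limma fit 3 genes were called higher and 150 lower of 11037, 0 and 68 of them by at least 2-fold, against 270 and 1095 at an unadjusted p under 0.05. All arrays of one group lay above all of the other for 48.5% of the genes, where chance gives 33.3%.

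The other genes with the lowest fold changes were Sostdc1 (-2.07 ± 0.24), an inhibitor of BMP and Wnt signalling, the membrane glycoprotein gene Gpm6b (-2.03 ± 0.13), the MHC class Ib gene H2-Q1 (-2.03 ± 0.19), Marcks (-2.01 ± 0.20), a substrate of protein kinase C, the drug efflux pump gene Abcb1a (-1.64 ± 0.33), and Eea1 (-1.62 ± 0.27), of early endosomes. Sostdc1, H2-Q1 and Marcks lay under the array medians in injected mice. The higher genes were Mex3b, which encodes an RNA-binding protein (0.93 ± 0.14, adjusted p = 0.0119), Smim13 (0.72 ± 0.13, adjusted p = 0.0314), and the gene model Gm4129 (0.95 ± 0.16, adjusted p = 0.0196), which was chosen after its values were seen. Foxp3, the transcription factor of regulatory T cells, was not called (-0.28 ± 0.13, adjusted p = 0.442), nor were Il10 (-0.17 ± 0.36, adjusted p = 0.935), Ctla4 (-0.55 ± 0.39, adjusted p = 0.659) and Lag3 (-0.12 ± 0.10, adjusted p = 0.712).

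Of the T follicular helper genes, 0 of the 10 tested were called higher and 4 lower (0 and 7 adjusted over the list alone). Camera gave this list an adjusted p = 1.53e-09, and an adjusted p = 0.0701 with an estimated correlation. Beside Cxcr5 and Pdcd1, Il21 (-1.35 ± 0.28), a cytokine of these cells, and Bcl6 (-0.96 ± 0.19), their transcription factor, were lower. Other probe sets of Il21 and Bcl6 gave 0.16 and 0.04. The call of Bcl6 was lost without any 1 of the 4 arrays (adjusted p from 0.106 to 0.49), and that of Il21 without naive replicate 1 (0.187) or 2 (0.389) or injected replicate 1 (0.19). Of the B cell markers, 0 of the 9 tested were called higher and 4 lower (0 and 6 adjusted over the list alone). For the list, camera gave an adjusted p = 3.22e-06, and an adjusted p = 0.109 with an estimated correlation. The members that fell were H2-Aa, Cd74 (-1.39 ± 0.22), the invariant chain of MHC class II, Ly86 (-1.34 ± 0.22) and Cd22 (-1.02 ± 0.14). These MHC class II genes serve antigen presentation and are not limited to B cells, and Ighm, the immunoglobulin heavy chain gene of B cells, lay at 4.05 in naive mice, under the array medians. Of the myeloid and dendritic cell markers, 0 of the 18 tested were called higher and 5 lower (0 and 11 adjusted over the list alone). The test of the list gave an adjusted p = 4.51e-09, and an adjusted p = 0.0701 with an estimated correlation. The called members were Ifi30 (-1.28 ± 0.25), a thiol reductase of antigen processing, Cybb (-1.27 ± 0.19), a subunit of the phagocyte oxidase, Itgax (-1.12 ± 0.11), which encodes CD11c of dendritic cells, Adgre1 (-0.85 ± 0.15), which encodes the macrophage marker F4/80, and 1 more.

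**Figure D3:**
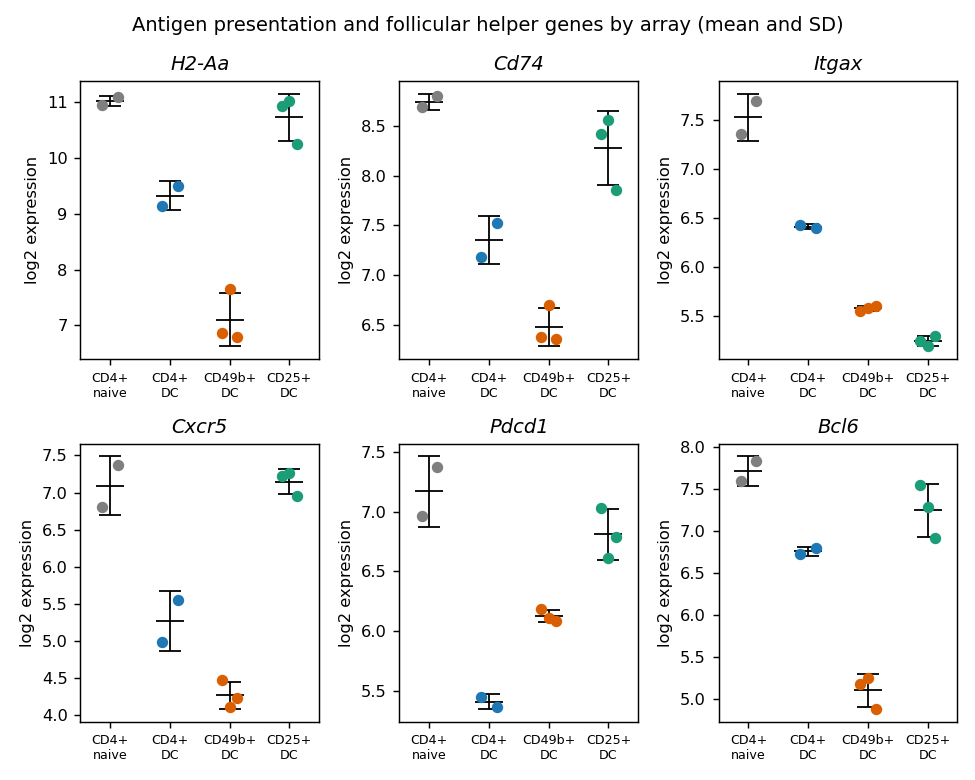
Log2 expression (y axis) of 6 genes in each array (points) of the 4 groups (x axis), with the group mean and SD (bars). H2-Aa stands at a mean of 11.03 in CD4+ cells of naive mice, 9.32 in those of injected mice, 7.10 in CD49b+ and 10.73 in CD25+ cells.

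Of the regulatory T cell signature, 0 of the 28 tested were called higher and 5 lower (0 and 15 adjusted over the list alone). Tested as a list, they had an adjusted p = 5.62e-10, and an adjusted p = 0.116 with an estimated correlation. Its lowest members were Gpm6b, Nt5e (-1.6 ± 0.20), which encodes the ectoenzyme CD73, Fgl2 (-1.56 ± 0.18) and Nrp1 (-1.35 ± 0.15). Nt5e and Fgl2 were also the members called among the suppressive effector molecules (0 higher and 2 lower of 16 tested, 0 and 4 adjusted over the list alone; adjusted p = 8.47e-05, and adjusted p = 0.0701 with an estimated correlation). Of the effector and memory T cell genes, 0 of the 24 tested were called higher and 4 lower (0 and 10 adjusted over the list alone), led by Casp1 (-1.34 ± 0.19), S100a4 (-1.31 ± 0.22) and Itgb1 (-1.07 ± 0.19). As a list these genes had an adjusted p = 7.25e-08, and an adjusted p = 0.175 with an estimated correlation. Of the T helper 17 genes, 0 of the 10 tested were called higher and 3 lower (0 and 7 adjusted over the list alone). With camera the list had an adjusted p = 7.4e-05, and an adjusted p = 0.116 with an estimated correlation. The T helper 17 genes that fell were Tmem176b (-1.37 ± 0.25), Tmem176a (-1.16 ± 0.21) and Il21. The type 1 regulatory T cell genes (0 higher and 3 lower of 19 tested, 0 and 7 adjusted over the list alone) were called lower as a list in camera, with an adjusted p = 0.000748, and adjusted p = 0.116 with an estimated correlation. Their called members were Pdcd1, Il21 and Maf (-0.82 ± 0.11).

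The remaining list calls rested on few or no called members. Pdcd1 was the called one of the coinhibitory receptors (0 higher and 1 lower of 11 tested, 0 and 4 adjusted over the list alone; adjusted p = 3.44e-05, and adjusted p = 0.0701 with an estimated correlation). Il18r1 (-0.64 ± 0.09) was the member called among the natural killer T cell markers (0 higher and 1 lower of 12 tested, 0 and 4 adjusted over the list alone; adjusted p = 0.00242, and adjusted p = 0.116 with an estimated correlation). It was also the one called among the T helper 1 genes (0 higher and 1 lower of 12 tested, 0 and 3 adjusted over the list alone; adjusted p = 0.00536, and adjusted p = 0.156 with an estimated correlation). The gamma-delta T cell markers (0 higher and 3 lower of 7 tested, 0 and 3 adjusted over the list alone; adjusted p = 0.0131, and adjusted p = 0.116 with an estimated correlation) shared Tmem176a, Tmem176b and Maf with other lists. No member was called of the cell cycle genes, whose median was -0.32 (adjusted p = 0.0225, and adjusted p = 0.67 with an estimated correlation). None was called of the immediate early and stress genes, with a median of 0.44 (adjusted p = 0.000928, and adjusted p = 0.317 with an estimated correlation). The same held for the naive and quiescent T cell genes, with a median of 0.18 (adjusted p = 0.00894, and adjusted p = 0.158 with an estimated correlation). It held for the T helper 2 genes, with a median of 0.08 (adjusted p = 0.0275, and adjusted p = 0.116 with an estimated correlation). The other 10 lists tested were not called, with adjusted p from 0.0702 to 0.903. Among them, 0 of 22 interferon-stimulated genes (adjusted p = 0.903) and 0 of 7 CD8 T cell markers (adjusted p = 0.66) were called, the latter with a median of 0.04 and a mean of -0.03.

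The first comparison rested on single arrays and on the spread borrowed from the other groups. In limma 0 genes were called higher and 0 lower when the 4 arrays were fitted alone (432 and 1305 at an unadjusted p under 0.05). The lower genes numbered 16 without naive replicate 2, 30 without injected replicate 1, 101 without naive replicate 1 and 114 without injected replicate 2. Centring each array on its median moved the median of all genes by 0.10 and gave 16 higher and 106 lower, so that 13.1% of the calls were higher instead of 1.96%. Of the 31 called genes named here, 20 were still called without naive replicate 1, 6 without naive replicate 2, 11 without injected replicate 1 and 22 without injected replicate 2. Those of Pdcd1, Gpm6b, H2-Q1, Itgax, Marcks and Sostdc1, 6 in all, were kept whichever of the 4 arrays was left out, and those of H2-Aa, Bcl6, Mex3b, Smim13 and Tmem176a, 5 in all, were lost without any 1 of them. Of the 15 called genes with other probe sets, 10 had no other one called the same way when adjusted over all probe sets, namely Abcb1a, Bcl6, Cybb, Fgl2, Fscn1, Il21, Itgb1, Nt5e, Sostdc1 and Tmem176a. Fry, which asks another question than camera, did not call the T helper 2 (adjusted p = 0.136) or the naive and quiescent T cell genes (0.271). Nor did it call the immediate early and stress genes (0.44) or the cell cycle genes (0.44). The calls of the naive and quiescent T cell genes (adjusted p = 0.103) and the T helper 1 genes (0.0938) were lost without injected replicate 1, and that of the cell cycle genes without that array (0.305) or naive replicate 2 (0.149). Those of the immediate early and stress genes (0.053) and the gamma-delta T cell markers (0.053) were lost without injected replicate 2. That of the T helper 2 genes was lost without injected replicate 2 (0.181) or naive replicate 1 (0.0546), with no filter on dim genes (0.103) and with quantile normalization (0.0504). The T cell receptor activation targets were called higher without injected replicate 1 (adjusted p = 0.0266). The chemokine receptors were called lower without naive replicate 1 (0.0323), and the glycolysis genes without injected replicate 2 (0.0466).

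The second comparison set CD49b+ cells against CD4+ cells, both of injected mice, a profile that per the labels holds the transcripts of the subset and those that the injections induced. In CD49b+ cells 23 of 24 effector and memory T cell genes and 32 of 35 cell cycle genes were called higher, and 12 of 13 naive and quiescent T cell genes lower. These list calls did not hold with an estimated correlation (adjusted p = 0.181, 0.271 and 0.181). With fry, which asks only whether members changed, the adjusted p were 1.16e-05, 0.000248 and 6.68e-06. Ccr2, a receptor for inflammatory chemokines, was higher by 5.28 ± 0.41 on the log2 scale (SE, n = 3 and 2; adjusted p = 8.41e-06), or 38.8-fold, and Gzmb, the cytotoxic protease granzyme B, by 5.22 ± 0.21, adjusted p = 1.73e-07. Klrg1, an inhibitory receptor of differentiated T cells, was higher by 5.11 ± 0.14, adjusted p = 4.62e-08, and Pparg, a nuclear receptor of lipid metabolism, by 4.82 ± 0.18, adjusted p = 1.06e-07. In CD4+ cells Gzmb (4.45) and Pparg (4.04) lay under the array medians. Igfbp4 was the lowest gene, at -4.23 ± 0.15, adjusted p = 6.58e-08. Foxp3 was higher by 1.81 ± 0.12, adjusted p = 3.18e-06, from a level of 4.64 in CD4+ cells, also under the medians.

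In limma, 3300 genes were called higher and 2592 lower, 778 and 288 of them by at least 2-fold. All arrays of one group lay above all of the other for 70.3% of the genes, where chance gives 20%. The other genes with the highest fold changes were AA467197 (5.04 ± 0.17), the leukotriene receptor gene Cysltr1 (5.0 ± 0.15), Prxl2a (4.88 ± 0.28), the mitotic ubiquitin-conjugating enzyme gene Ube2c (4.73 ± 0.49), the chemokine receptor gene Cxcr6 (4.58 ± 0.42) and Ltb4r1 (4.51 ± 0.24), a receptor for leukotriene B4. AA467197, Cysltr1 and Ltb4r1 lay under the array medians in CD4+ cells, as did Arhgap29, Lypd6b and Amigo2 in CD49b+ cells. The lowest after Igfbp4 were Arhgap29 (-3.38 ± 0.10), Lypd6b (-3.36 ± 0.12), Atp1b1 (-3.31 ± 0.12), Tubb2a (-3.22 ± 0.16), Actn1 (-3.1 ± 0.10), Bach2 (-3.09 ± 0.28), a repressor of effector differentiation, Sox4 (-3.0 ± 0.26), Amigo2 (-2.98 ± 0.15) and Als2cl (-2.96 ± 0.14). Il10 (0.63 ± 0.33, adjusted p = 0.131), Ctla4 (0.67 ± 0.35, adjusted p = 0.133) and Lag3 (-0.16 ± 0.09, adjusted p = 0.162) were not called. More members of lists that hold these genes were called with the replicate number as a block. Type 1 regulatory T cell genes then numbered 13 higher and 2 lower, instead of 11 and 1. Suppressive effector molecules numbered 12 and 2, instead of 10 and 1. Ctla4 was called higher without CD49b+ replicate 3 (0.99, adjusted p = 0.0258). Without replicate 3 of both subsets, a setting chosen after seeing the data, Ctla4 (adjusted p = 0.00312) and Il10 (0.84, adjusted p = 0.00974) were called higher. Lag3 was called lower with the arrays centred on their medians (-0.35, adjusted p = 0.0108).

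Of the effector and memory T cell genes, 23 of the 24 tested were called higher and 0 lower (23 and 1 adjusted over the list alone). In camera they had an adjusted p = 2.72e-11, and an adjusted p = 0.181 with an estimated correlation. Ccr2, Cxcr6, Anxa1 (4.14 ± 0.15) and Lgals3 (4.07 ± 0.17) led them. Of the cell cycle genes, 32 of the 35 tested were called higher and 0 lower (33 and 0 adjusted over the list alone), with Ube2c, Mki67 (4.19 ± 0.26), the proliferation marker Ki-67, and Tpx2 (4.08 ± 0.35) of the mitotic spindle among the highest. Camera gave this list an adjusted p = 5.87e-12, and an adjusted p = 0.271 with an estimated correlation. Of the naive and quiescent T cell genes, 1 of the 13 tested were called higher and 12 lower (1 and 12 adjusted over the list alone). For the list, camera gave an adjusted p = 3.67e-06, and an adjusted p = 0.181 with an estimated correlation. Igfbp4, Actn1 and Bach2 were the lowest, and Ccr9 (2.97 ± 0.31), a gut-homing chemokine receptor, was the member called higher. Another probe set of Ccr9 was called higher too (2.33, adjusted p = 0.002), and a dim one at a mean level of 3.85 gave -0.16. Of the regulatory T cell signature, 23 of the 28 tested were called higher and 3 lower (23 and 3 adjusted over the list alone), led by Klrg1, Itgae (3.66 ± 0.17) and Socs2 (3.62 ± 0.19). The test of the list gave an adjusted p = 2.22e-08, and an adjusted p = 0.181 with an estimated correlation. Another probe set of Socs2 was called higher too (4.7, adjusted p = 4.27e-07), and a dim one at a mean level of 3.57 gave -0.03.

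T helper lists were called as well. Of the T helper 1 genes, 8 of the 12 tested were called higher and 1 lower (8 and 1 adjusted over the list alone), among them Tbx21 (3.81 ± 0.41), the transcription factor T-bet, and Ifng (1.59 ± 0.53). Tested as a list, they had an adjusted p = 0.0144, and an adjusted p = 0.219 with an estimated correlation. The call of Ifng was lost without CD4+ replicate 1 (0.93, adjusted p = 0.24) or CD49b+ replicate 1 (0.079) or 2 (0.0821). Of the T helper 2 genes, 6 of the 7 tested were called higher and 1 lower (6 and 1 adjusted over the list alone), among them Gata3 (2.68 ± 0.14) and Il4 (2.63 ± 0.30). As a list these genes had an adjusted p = 0.0149, and an adjusted p = 0.181 with an estimated correlation. The T helper 17 genes (6 higher and 1 lower of 10 tested, 6 and 1 adjusted over the list alone; adjusted p = 0.0149, and adjusted p = 0.275 with an estimated correlation) were led by Ahr (4.13 ± 0.19), the aryl hydrocarbon receptor, of which another probe set gave -0.01. Of the type 1 regulatory T cell genes, 11 of the 19 tested were called higher and 1 lower (11 and 1 adjusted over the list alone), with Gzmb, Ahr and Maf (3.1 ± 0.10) the highest. With camera the list had an adjusted p = 0.00168, and an adjusted p = 0.181 with an estimated correlation. The suppressive effector molecules (10 higher and 1 lower of 16 tested, 10 and 2 adjusted over the list alone; adjusted p = 0.00455, and adjusted p = 0.181 with an estimated correlation) were led by Gzmb, Fgl2 (3.0 ± 0.17) and Ebi3 (2.59 ± 0.21). Of the natural killer T cell markers, 9 of the 12 tested were called higher and 1 lower (9 and 1 adjusted over the list alone). They were led by Cxcr6 and Tbx21, which are also in other lists, and Plac8 (3.3 ± 0.28). In camera the list had an adjusted p = 0.000403, and an adjusted p = 0.181 with an estimated correlation.

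Of the chemokine receptors, 8 of the 9 tested were called higher and 1 lower (8 and 1 adjusted over the list alone). Camera gave this list an adjusted p = 0.00122, and an adjusted p = 0.181 with an estimated correlation. The integrins (8 higher and 1 lower of 11 tested, 9 and 1 adjusted over the list alone; adjusted p = 0.0145, and adjusted p = 0.198 with an estimated correlation) were led by Itgae and Itgb1 (2.94 ± 0.17). The glycolysis genes (11 higher and 1 lower of 12 tested, 11 and 1 adjusted over the list alone) were led by Slc2a3 (1.79 ± 0.10) and Tpi1 (1.55 ± 0.17). In camera this list had an adjusted p = 0.000984, and an adjusted p = 0.181 with an estimated correlation. Another bright probe set of Slc2a3 was called higher too (2.0, adjusted p = 5.55e-06), and a dim one at a mean level of 3.71 gave -0.07. The cholesterol synthesis genes (11 higher and 2 lower of 16 tested, 11 and 2 adjusted over the list alone; adjusted p = 0.0145, and adjusted p = 0.34 with an estimated correlation) were led by Ebp (1.55 ± 0.12). Of the B cell markers, 1 of the 9 tested were called higher and 6 lower (1 and 6 adjusted over the list alone). For the list, camera gave an adjusted p = 0.0145, and an adjusted p = 0.271 with an estimated correlation. H2-Ab1 (-2.43 ± 0.35), H2-Aa (-2.22 ± 0.29) and Ly86 (-2.18 ± 0.20) were the lowest. The other 11 lists tested were not called, with adjusted p from 0.0729 to 0.821. Among these were the natural killer cell markers, with 5 of 11 higher and 3 lower (adjusted p = 0.728) and Gzma (3.97 ± 0.26) among the higher, and the coinhibitory receptors, with 6 of 11 higher and 1 lower (adjusted p = 0.0729). The myeloid and dendritic cell markers, the T follicular helper genes and the platelet and megakaryocyte markers differed in sign between their median, mean and test.

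The CD49b+ and CD4+ arrays also differed in background and in the 3' to 5' difference of Gapdh given above, while that of Actb was 0.50 and 0.53. Centring each array on its median moved the median of all genes by -0.19 and gave 2191 higher and 4391 lower genes, 33.3% of the calls being higher instead of 56%. Without a filter on dim genes 3526 were higher and 5597 lower, and 2790 and 1230 with the stricter one.

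The third comparison set CD25+ cells against CD4+ cells of injected mice. In CD25+ cells 27 of 28 members of the regulatory T cell signature were called higher, a list call that did not hold with an estimated correlation (adjusted p = 0.13). With fry, which asks only whether members changed, the adjusted p was 5.98e-06. Beside Il2ra, Foxp3 was higher by 3.61 ± 0.12 on the log2 scale (SE, n = 3 and 2; adjusted p = 1.97e-07). Both lay under the array medians in CD4+ cells, Il2ra at 4.17 and Foxp3 at 4.64. Ctla4, an inhibitory receptor of these cells, was higher by 2.25 ± 0.35, adjusted p = 0.000883, and Il10, an anti-inflammatory cytokine, by 1.61 ± 0.33, adjusted p = 0.00379. The highest fold change was listed for the proteoglycan gene Sdc4 (4.93 ± 0.31, adjusted p = 3.36e-06), which lay at 4.38 in CD4+ cells, under the array medians, and that with the lowest Igfbp4 (-4.18 ± 0.15, adjusted p = 2.08e-07). Lag3 was not called (-0.06 ± 0.09, adjusted p = 0.658).

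In limma, 2297 genes were called higher and 1964 lower, 561 and 150 of them by at least 2-fold. All arrays of one group lay above all of the other for 58.9% of the genes, where chance gives 20%. The other genes with the highest fold changes were Penk (4.27 ± 0.18), which encodes the opioid precursor proenkephalin, Lgals3 (4.12 ± 0.17), the growth factor gene Bmp2 (3.94 ± 0.39), Coro2a (3.89 ± 0.14), Klrg1 (3.85 ± 0.14), Tnfrsf9 (3.81 ± 0.12), the costimulatory receptor 4-1BB, Itgae (3.75 ± 0.17) and Serpinb1a (3.75 ± 0.19). Bmp2, Itgae and Serpinb1a lay under the array medians in CD4+ cells, as did Arhgap29 and Hs3st3b1 in CD25+ cells. A dim probe set of Tnfrsf9, at a mean level of 3.81, was called the opposite way (-0.34, adjusted p = 0.00399). A brighter one was called higher too (3.03, adjusted p = 5.65e-06). The lowest after Igfbp4 were Pdlim4 (-4.11 ± 0.24), Tdrp (-3.37 ± 0.16), Vipr1 (-3.36 ± 0.15), Arhgap29 (-3.17 ± 0.10), Lypd6b (-2.96 ± 0.12), Hs3st3b1 (-2.88 ± 0.28), Enc1 (-2.74 ± 0.20), Adh1 (-2.5 ± 0.12) and the receptor gene Ntrk3 (-2.4 ± 0.12). Among the dimmer probe sets of Ntrk3, one was called lower too (-0.97, adjusted p = 8.43e-05) and another gave 0.06.

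Of the regulatory T cell signature, 27 of the 28 tested were called higher and 1 lower (27 and 1 adjusted over the list alone). The test of the list gave an adjusted p = 1.98e-20, and an adjusted p = 0.13 with an estimated correlation. Of the type 1 regulatory T cell genes, 13 of the 19 tested were called higher and 2 lower (13 and 3 adjusted over the list alone), led by Maf (2.75 ± 0.10) and Ahr (2.68 ± 0.19). Tested as a list, they had an adjusted p = 0.000121, and an adjusted p = 0.13 with an estimated correlation. Another probe set of Ahr gave -0.22. Of the suppressive effector molecules, 11 of the 16 tested were called higher and 1 lower (11 and 1 adjusted over the list alone), led by Penk, Ebi3 (2.68 ± 0.21), a cytokine subunit, and Nt5e (2.6 ± 0.18), another probe set of which was called the opposite way (-0.32, adjusted p = 0.0112). As a list these genes had an adjusted p = 0.000121, and an adjusted p = 0.13 with an estimated correlation. The coinhibitory receptors (7 higher and 1 lower of 11 tested, 7 and 1 adjusted over the list alone; adjusted p = 0.00948, and adjusted p = 0.154 with an estimated correlation) were led by Klrg1, Ctla4 and Cd160 (2.0 ± 0.14). Of the cell cycle genes, 32 of the 35 tested were called higher and 1 lower (33 and 1 adjusted over the list alone), with Ube2c (3.45 ± 0.49) and Mki67 (3.19 ± 0.26) the highest. With camera the list had an adjusted p = 5.94e-11, and an adjusted p = 0.288 with an estimated correlation. Of the effector and memory T cell genes, 19 of the 24 tested were called higher and 0 lower (19 and 0 adjusted over the list alone), led by Lgals3 and Anxa1 (3.12 ± 0.15). In camera they had an adjusted p = 2.94e-09, and an adjusted p = 0.208 with an estimated correlation. Of the naive and quiescent T cell genes, 2 of the 13 tested were called higher and 9 lower (2 and 9 adjusted over the list alone), with Igfbp4 and Lef1 (-2.16 ± 0.29), a transcription factor of naive T cells, the lowest. Camera gave this list an adjusted p = 0.000243, and an adjusted p = 0.13 with an estimated correlation.

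Of the T helper 17 genes, 7 of the 10 tested were called higher and 2 lower (7 and 3 adjusted over the list alone), led by Tmem176a (3.62 ± 0.19) and the chemokine receptor gene Ccr6 (2.91 ± 0.17). For the list, camera gave an adjusted p = 0.00309, and an adjusted p = 0.232 with an estimated correlation. Of the natural killer T cell markers, 9 of the 12 tested were called higher and 0 lower (9 and 0 adjusted over the list alone). They were led by Il2rb (3.08 ± 0.15) and Cxcr6 (2.62 ± 0.42), which are also in other lists. The test of the list gave an adjusted p = 0.000121, and an adjusted p = 0.13 with an estimated correlation. The chemokine receptors (6 higher and 0 lower of 9 tested, 6 and 0 adjusted over the list alone; adjusted p = 0.00479, and adjusted p = 0.155 with an estimated correlation) were also called higher. So were the glycolysis genes (8 higher and 1 lower of 12 tested, 8 and 1 adjusted over the list alone; adjusted p = 0.00703, and adjusted p = 0.246 with an estimated correlation), and the gamma-delta T cell markers (4 higher and 0 lower of 7 tested, 4 and 0 adjusted over the list alone; adjusted p = 0.00765, and adjusted p = 0.147 with an estimated correlation). The T helper 1 genes (6 higher and 1 lower of 12 tested, 6 and 1 adjusted over the list alone; adjusted p = 0.0295, and adjusted p = 0.259 with an estimated correlation) were higher too, a call lost without CD4+ replicate 1 (adjusted p = 0.0654). The other 13 lists tested were not called, with adjusted p from 0.0807 to 0.749. Among them were the T follicular helper genes, 4 of 10 higher, and the B cell markers, 3 of 9 higher and 1 lower, with H2-Aa (1.41 ± 0.29) and Cd74 (0.93 ± 0.20) higher than in CD4+ cells of injected mice. H2-Aa, Cd74 and Pdcd1 (1.41 ± 0.14) turned direction against CD4+ cells of naive mice, at -0.29, -0.46 and -0.36, none of these called, and the call of Cd74 was lost without CD4+ replicate 1 (0.76, adjusted p = 0.0548). The integrins were called without CD25+ replicate 2 (adjusted p = 0.0384), and the T cell receptor activation targets without CD4+ replicate 2 (0.0136) or CD25+ replicate 3 (0.0224). The erythroid, the myeloid and dendritic cell, the CD8 T cell, the platelet and megakaryocyte and the immediate early and stress lists differed in sign between their median, mean and test.

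The lower genes numbered 1285 without CD4+ replicate 1 and 1249 without CD4+ replicate 2, and centring each array on its median moved the median of all genes by -0.15 and gave 1528 higher and 3392 lower genes, 31.1% of the calls being higher instead of 53.9%. Background and the 3' to 5' difference of Gapdh differed between these groups too, with Actb at 0.64 and 0.53. Without a filter on dim genes 2602 were higher and 4981 lower, against 1801 and 699 with the stricter one.

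The fourth comparison set the subsets against each other. In CD49b+ cells 17 of 24 effector and memory T cell genes were called higher, and 17 of 28 members of the regulatory T cell signature and 7 of 9 B cell markers, among them genes of MHC class II, lower. These list calls did not hold with an estimated correlation (adjusted p = 0.512, 0.425 and 0.425). With fry, which asks only whether members changed, the adjusted p were 0.00402, 0.000838 and 0.000838. Pparg was higher in CD49b+ cells by 4.22 ± 0.16 on the log2 scale (SE, n = 3 and 3; adjusted p = 2.97e-07), from a level of 4.64 in CD25+ cells, at the array medians. Ccr2 was higher by 3.61 ± 0.37, adjusted p = 7.76e-05, Gzmb by 3.04 ± 0.19, adjusted p = 3.21e-06 and Il4, the T helper 2 cytokine, by 2.42 ± 0.27, adjusted p = 0.000136. Foxp3 was lower in CD49b+ cells at -1.8 ± 0.11, adjusted p = 2.97e-06, and Il2ra at -2.54 ± 0.13, adjusted p = 1.12e-06. Ctla4 was lower at -1.58 ± 0.31, adjusted p = 0.00417 and Il10 at -0.98 ± 0.29, adjusted p = 0.0295. The call of Il10 was lost without CD49b+ replicate 1 (adjusted p = 0.0624) or 3 (-0.77, 0.104), or CD25+ replicate 1 (0.0859) or 2 (-0.67, 0.0792). H2-Aa was lower at -3.63 ± 0.26, adjusted p = 7.06e-06. Lag3 was not called (-0.10 ± 0.08, adjusted p = 0.385).

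In limma, 1926 genes were called higher in CD49b+ than in CD25+ cells and 1371 lower, 277 and 285 of them by at least 2-fold. All arrays of one group lay above all of the other for 41.6% of the genes, where chance gives 10%. The other genes with the highest fold changes were Pdlim4 (4.01 ± 0.21), Plac8 (3.84 ± 0.25), Prxl2a (3.68 ± 0.25), AA467197 (3.5 ± 0.16), Ltb4r1 (3.4 ± 0.22), Ctla2b (3.37 ± 0.22), the hypoxia-inducible factor gene Epas1 (3.2 ± 0.19) and Tmem273 (3.11 ± 0.16). Those with the lowest were the zinc finger gene Plagl1 (-4.01 ± 0.20), Bmp2 (-3.99 ± 0.35), the potassium channel gene Kcnk1 (-3.68 ± 0.20), Sdc4 (-3.49 ± 0.28), Tubb2a (-3.48 ± 0.14), Cd83 (-3.46 ± 0.26), H2-Ab1 (-3.22 ± 0.31), Ephx1 (-3.19 ± 0.08) and Ift80 (-3.1 ± 0.12). Tmem273 lay under the array medians in CD25+ cells, as did Plagl1, Bmp2 and Kcnk1 in CD49b+ cells. Dimmer probe sets of Plagl1 (-0.20), Tmem273 (0.11) and Tubb2a (0.00) were not called.

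Of the regulatory T cell signature, 3 of the 28 tested were called higher and 17 lower (4 and 19 adjusted over the list alone). Tested as a list, they had an adjusted p = 1.94e-07, and an adjusted p = 0.425 with an estimated correlation. Plagl1, Cd83, Il2ra and Tnfrsf9 (-2.29 ± 0.11) were the lowest. Of the effector and memory T cell genes, 17 of the 24 tested were called higher and 1 lower (18 and 1 adjusted over the list alone), led by Ccr2 and Cxcr6 (1.96 ± 0.38). As a list these genes had an adjusted p = 1.08e-05, and an adjusted p = 0.512 with an estimated correlation. Of the B cell markers, 0 of the 9 tested were called higher and 7 lower (0 and 8 adjusted over the list alone), with H2-Aa, H2-Ab1 and Cd74 (-1.81 ± 0.18) the lowest. With camera the list had an adjusted p = 4.18e-05, and an adjusted p = 0.425 with an estimated correlation. Of the cell cycle genes, 19 of the 35 tested were called higher and 0 lower (24 and 0 adjusted over the list alone), led by Tpx2 (1.44 ± 0.32) and Ccnb2 (1.32 ± 0.33). In camera they had an adjusted p = 4.3e-05, and an adjusted p = 0.709 with an estimated correlation. The naive and quiescent T cell genes (2 higher and 6 lower of 13 tested, 2 and 6 adjusted over the list alone) were called lower as a list in camera (adjusted p = 0.00892, and adjusted p = 0.425 with an estimated correlation), with Bach2 (-2.62 ± 0.25) the lowest. The cholesterol synthesis genes (7 higher and 0 lower of 16 tested, 7 and 0 adjusted over the list alone) were called higher as a list in camera (adjusted p = 0.0163, and adjusted p = 0.634 with an estimated correlation). The T cell receptor activation targets (2 higher and 7 lower of 17 tested, 2 and 7 adjusted over the list alone) were called lower as a list in camera (adjusted p = 0.036, and adjusted p = 0.709 with an estimated correlation), with Tnfrsf9 and Nr4a3 (-1.68 ± 0.24) the lowest. The other probe sets of Nr4a3, one of them nearly as bright, gave -0.05 and -0.06 and were not called. The list call was lost without CD49b+ replicate 1 (adjusted p = 0.0535) or 3 (0.114), or CD25+ replicate 1 (0.0563) or 2 (0.0784). Fry, which asks another question than camera, gave this list an adjusted p = 0.0572.

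Of the T helper 2 genes, 4 of the 7 tested were called higher and 0 lower (4 and 0 adjusted over the list alone), with Il4 and Gata3 (1.43 ± 0.13) the highest. Camera gave this list an adjusted p = 0.0494, and an adjusted p = 0.425 with an estimated correlation. This call was lost with the replicate number as a block (adjusted p = 0.0731) and without CD49b+ replicate 1 (0.0645) or 2 (0.0932), or CD25+ replicate 2 (0.0784) or 3 (0.0609). The chemokine receptors (7 higher and 2 lower of 9 tested, 7 and 2 adjusted over the list alone; adjusted p = 0.0666, and adjusted p = 0.512 with an estimated correlation) were called with the block (adjusted p = 0.0463), without CD25+ replicate 3 (0.0117), without replicate 3 of both subsets (0.00743) and with no filter on dim genes (0.0311), with Cxcr5 (-2.88 ± 0.18) lower. The other 17 lists tested were not called, with adjusted p from 0.0817 to 0.985. They included the T follicular helper genes, 4 of 10 higher and 5 lower with Bcl6 (-2.14 ± 0.16) among the lower, the type 1 regulatory T cell genes, 6 of 19 higher and 4 lower (adjusted p = 0.822), the integrins, 4 of 11 higher and 1 lower (adjusted p = 0.399), and the interferon-stimulated genes, 7 of 22 higher and 3 lower (adjusted p = 0.722). The erythroid markers (0 higher and 1 lower of 6 tested, 0 and 1 adjusted over the list alone; adjusted p = 0.173) and the platelet and megakaryocyte markers (1 higher and 1 lower of 7 tested, 1 and 1 adjusted over the list alone; adjusted p = 0.985) held few called members. The latter and the myeloid and dendritic cell markers differed in sign between their median and mean. Only 3 neutrophil and basophil markers were tested, of which 1 was lower in CD49b+ than in CD4+ cells and 0 were called in the other comparisons.

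**Figure D4:**
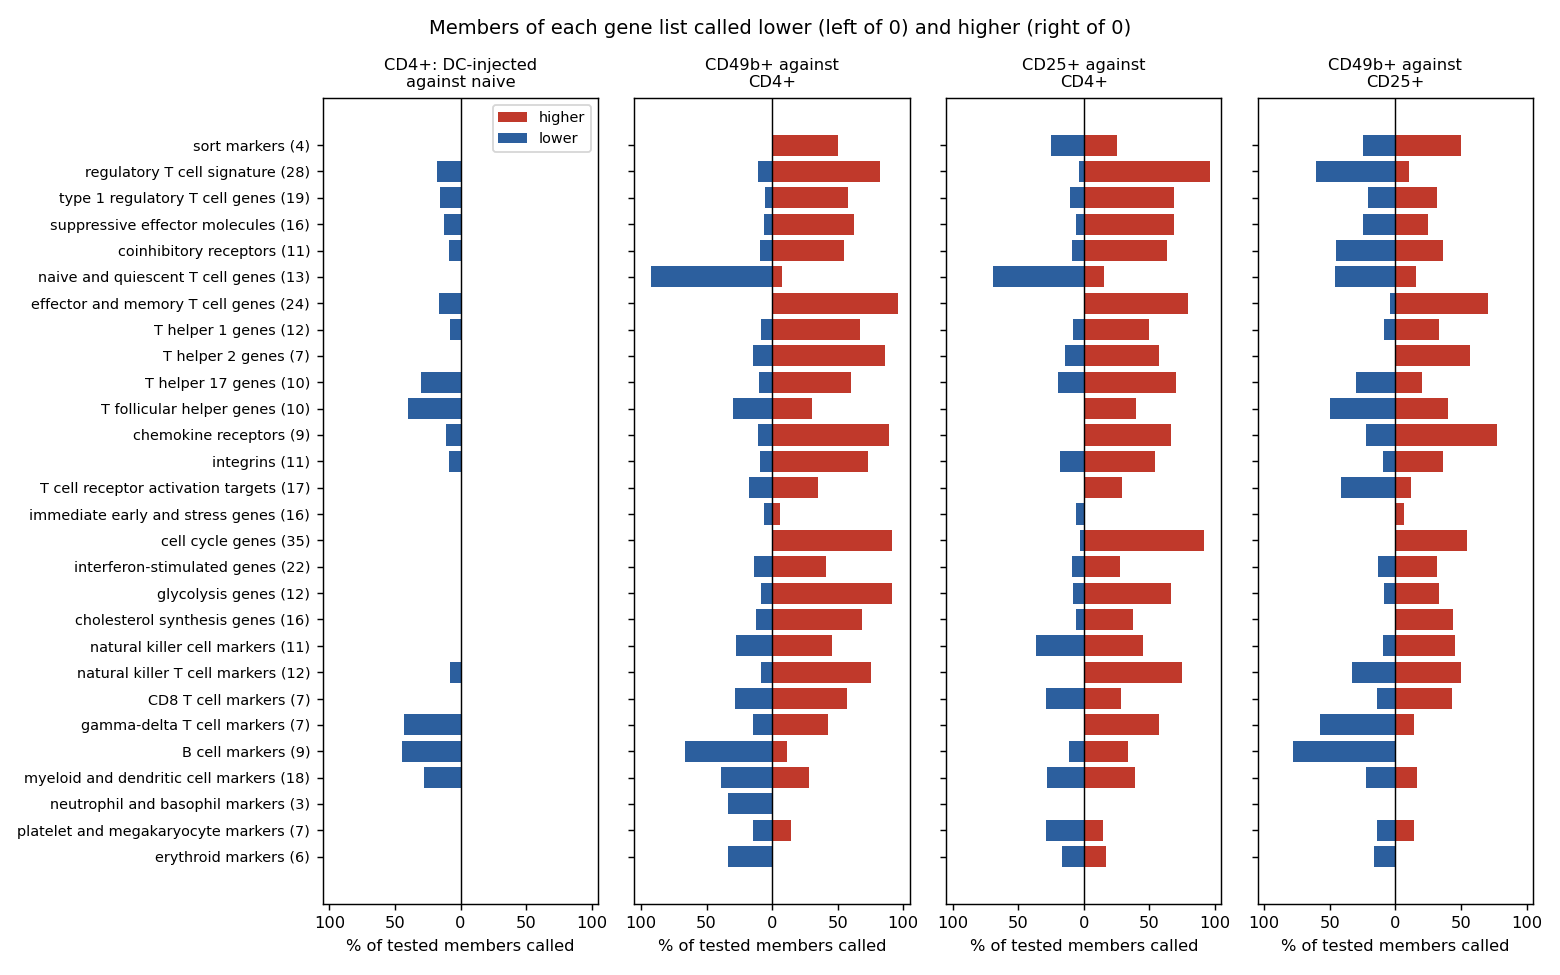
Percent of the tested members of each of the 28 gene lists (number tested in brackets) that were called higher (right of 0) or lower (left of 0) in each of the 4 comparisons (x axes, in percent). Of the regulatory T cell signature, 27 of 28 were higher in CD25+ than in CD4+ cells and 17 of 28 were lower in CD49b+ than in CD25+ cells.

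The profiles of both subsets against CD4+ cells were set side by side. They shared 1708 genes called higher and 1540 called lower, and 162 genes were called in opposite directions. Lists of these sizes drawn independently would share 686.8 and 461.2, with 1127 opposite. Simulated groups with no effect shared 0, a count that bears on no excess since at most 1 gene was called in any of the 100 simulations of either comparison. Klrg1 and Igfbp4 are examples called the same way in both, and H2-Aa was lower in CD49b+ (-2.22 ± 0.29) and higher in CD25+ cells (1.41 ± 0.29). Across genes, which are not independent replicates, the correlation of the fold changes was 0.708 ± 0.06 (jackknife SE over 8 arrays) against 0.598 with no effect. It was not above the 0.753 of a simulation with no effect, added after seeing the data. In that simulation same-numbered CD49b+ and CD25+ arrays deviated together as they did here. A correlation takes no account of the size of the changes, so it cannot tell shared changes from shared noise here. The covariance was 0.281 ± 0.0442 (jackknife SE) against 0.0156 and 0.0195 in these simulations. Part of the overlap beyond that of independent lists may come from the shared CD4+ arrays. The simulations shared these arrays too, so the spread of these arrays is already in the 0.0156 and 0.0195. Both subsets also had a lower background than CD4+ cells, at -0.112 in CD49b+ and -0.145 in CD25+ cells in the nonspecific control probe sets. The simulations held no such common shift, and its part in the overlap was not tested. With 1 CD4+ array for each subset, the genes called the same way numbered 1938 or 2075, against 3248 with both. They numbered 2124 without CD4+ replicate 1.

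**Figure D5:**
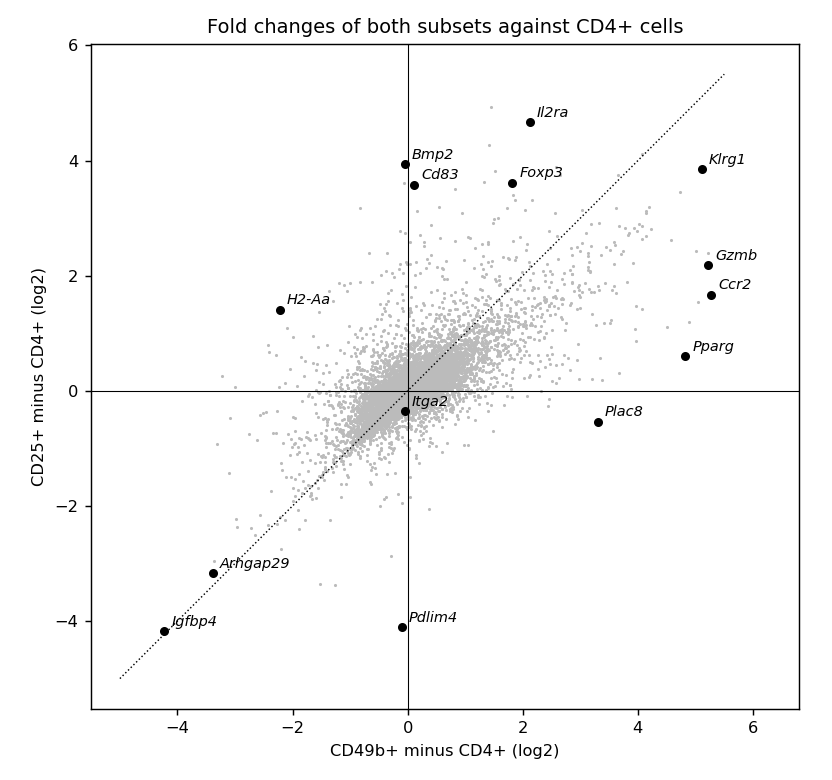
Log2 fold change of each of the 11037 genes (points) in CD49b+ (x axis) and CD25+ (y axis) against CD4+ cells of injected mice, with equal changes on the dotted line and some named genes in black. Igfbp4 lies at -4.23 and -4.18, Foxp3 at 1.81 and 3.61, and Pparg at 4.82 on the x axis.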

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

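The arrays left out in turn, the scalings, the filters and the block were planned, and the omission of both replicate 3 arrays, the poly-A covariate and the crossed pairing were chosen after the results were seen. Of the values of named genes under the alternatives, 513 of 727 kept direction and side of the threshold between the CD4+ groups, 1089 of 1127 in CD49b+ and 908 of 945 in CD25+ against CD4+ cells, and 715 of 744 between the subsets. For the lists, the estimated correlation apart, these were 202 of 234, 242 of 260, 237 of 260 and 251 of 286. All list values that turned in sign were of lists not called, 8, 6, 8 and 10 in the same order. Unless fewer genes or arrays were tested, the cause was not tested. Signal over background limits the dim genes, and how their calls depend on scaling was not tested.

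Between the CD4+ groups, the higher genes numbered 7 with quantile normalization, 16 with centring on medians, 7 with the trended robust prior, 5 with the mean of the probe sets, 6 over all probe sets and 0 by at least 2-fold. The lower genes by at least 2-fold numbered 68. Array weights gave 26 higher and 302 lower, the replicate block 57 and 320, the 4 arrays alone 0 and 0, the poly-A covariate 63 and 251, and the omission of both replicate 3 arrays 17 higher. With the 4 arrays alone, the replicate block gave 0 and 0 and the crossed pairing, tried because same-numbered arrays deviated by a correlation of -0.209, gave 0 and 0. Leaving out 1 array gave between 0 and 2 higher and between 16 and 114 lower.

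In CD49b+ against CD4+ cells, centring gave 2191 higher and 4391 lower, all probe sets 5797 and 6842, and the 2-fold threshold 778 and 288. The lower genes numbered 5597 without the filter on dim genes and 1230 with the stricter one. In CD25+ against CD4+ cells centring gave 1528 and 3392, all probe sets 3870 and 4899, and the 2-fold threshold 561 and 150. The lower genes numbered 4981 and 699 with the filters in the same order, and between 1249 and 1919 with 1 array left out. Between the subsets all probe sets gave 3140 and 2537, and the 2-fold threshold 277 and 285. The genes called the same way in both subsets numbered 476 by at least 2-fold, 1938 and 2075 with 1 CD4+ array each, and between 2124 and 3168 with 1 array left out. The correlation of fold changes was 0.638 with 1 CD4+ array each.

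No list was called with an estimated correlation, a count of 0, 0, 0 and 0 in the 4 comparisons, and fry called 16 between the subsets. The replicate numbers were taken to pair the CD49b+ and CD25+ arrays from the data alone, as the labels give no pairing. CD49b+ replicate 1 deviated with CD25+ replicate 2 (0.135) nearly as with CD25+ replicate 1 (0.158). The block there changed no call of a named gene and no list calls other than those of the T helper 2 genes and the chemokine receptors. For the other comparisons the labels give no pairing either. Same-numbered CD49b+ and CD4+ arrays of injected mice deviated by correlations of 0.0885 and 0.522, and CD25+ and CD4+ arrays by 0.244 and 0.531. Arrays of unlike number reached 0.446 there (CD49b+ replicate 3 with CD4+ replicate 1).

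Il2ra between the CD4+ groups, at -5e-06, turned to 0.10 with centring, 0.015 with the mean of its probe sets, 0.043 with the poly-A covariate, 0.029 in another probe set, and between -0.020 and 0.020 with 1 array left out. Cd3e there turned to -0.0053 with the poly-A covariate and ranged from -0.037 to 0.039 with 1 array left out. Other probe sets gave 0.036 for Bcl6, 0.031 for Fscn1 and 0.16 for Il21. In CD49b+ against CD4+ cells, Itga2 turned to 0.052 with quantile normalization, 0.052 against naive mice and 0.0017 against both CD4+ groups, and ranged from -0.14 to 0.043 with 1 array left out. Lag3 turned to 0.024 with quantile normalization, and Cd3e to -0.032 with centring. The Cd4 call was lost with centring (0.15), the mean of probe sets (0.14), the 2-fold threshold (0.34) and naive mice as the comparator (0.17), was -0.058 in another probe set, and ranged from 0.28 to 0.38. Dimmer probe sets gave -0.012 for Ahr, -0.16 for Ccr9, -0.075 for Slc2a3 and -0.028 for Socs2, while others of Ccr9, Slc2a3 and Socs2 were called higher.

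In CD25+ against CD4+ cells, Cd4 turned to -0.013 with quantile normalization, -0.11 with centring, -0.20 with the mean of probe sets, -0.13 against naive mice, -0.045 against both CD4+ groups and -0.45 in another probe set, a call, and ranged from -0.018 to 0.13. Cd3e ranged from -0.084 to 0.11, and Lag3 from -0.17 to 0.057, the latter at 0.079 with quantile normalization. Cd74, H2-Aa and Pdcd1 turned to -0.46, -0.29 and -0.36 against naive mice. The Itga2 call was lost with quantile normalization (-0.29), the 2-fold threshold (-0.36), naive mice (-0.26), both replicate 3 arrays out (-0.34) and the poly-A covariate (-0.32), and ranged from -0.39 to -0.33. Dimmer probe sets gave -0.22 for Ahr, -0.32 for Nt5e, 0.059 for Ntrk3 and -0.34 for Tnfrsf9, while others of Ntrk3 and Tnfrsf9 were called in the main direction. Between the subsets the Itga2 call was lost with centring (0.27), the 2-fold threshold and the 6 arrays alone (0.31), and both replicate 3 arrays out (0.29), and ranged from 0.21 to 0.40. The Cd4 call was lost with the 2-fold threshold and the 6 arrays alone (0.30) and both replicate 3 arrays out (0.24), and ranged from 0.21 to 0.36.

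The list means that follow had a test of the opposite sign to the main one. Between the CD4+ groups these were interferon-stimulated genes with the block and without both replicate 3 arrays (-0.0050), and CD8 T cell markers with fry (-0.028). With 1 array left out the T cell receptor activation targets ranged from -0.031 to 0.52, interferon-stimulated genes from -0.094 to 0.084, glycolysis genes from -0.20 to -0.015 and cholesterol synthesis genes from -0.13 to 0.027. In CD49b+ against CD4+ cells they were platelet markers with quantile normalization (0.18; 1 array left out, -0.042 to 0.11), T follicular helper genes with no filter (0.040) and fry (0.12), and immediate early genes with no filter (-0.049) and without both replicate 3 arrays (0.26). In CD25+ against CD4+ cells they were myeloid (0.16) and platelet markers (0.16) with quantile normalization, B cell markers with no filter (0.065), and immediate early genes with the block and with no filter (0.080) and without both replicate 3 arrays (0.34; 1 array left out, -0.17 to 0.34). Between the subsets they were type 1 regulatory T cell genes without both replicate 3 arrays (0.085; 1 array left out, 0.0086 to 0.17), platelet markers without both replicate 3 arrays (-0.054) and with no filter (-0.031; 1 array left out, -0.058 to 0.059), and interferon-stimulated genes with fry (-0.021; 1 array left out, -0.11 to 0.042). Immediate early genes ranged there from -0.38 to 0.18.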

Other observations

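The tests weighed here were chosen after the results were seen, except the count of other splits of the arrays.

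The natural killer cell markers went both ways in the subsets, and the list was not called in either. Of its members, CD49b+ cells held more Gzma (3.97 ± 0.26), which encodes granzyme A, and Nkg7 (2.78 ± 0.39) than CD4+ cells and less Tyrobp (-1.81 ± 0.28), an adaptor of natural killer cell receptors. CD25+ cells held more Fcer1g (1.9 ± 0.28) and less Klrd1 (-1.84 ± 0.34), which encodes CD94, and Tyrobp (-1.57 ± 0.28) (5 of 11 higher and 4 lower, adjusted p = 0.749 for the list). The interferon-stimulated genes also went both ways. In CD49b+ cells Isg20 (1.44 ± 0.19) and Mx1 (1.34 ± 0.14) were higher and Ifit2 (-1.17 ± 0.20) lower, and in CD25+ cells Gbp3 (1.97 ± 0.12) was higher and Oas2 (-0.92 ± 0.15) lower than in CD4+ cells. Of 22 members, 9 were higher and 3 lower in CD49b+, and 6 and 2 in CD25+ cells, and neither list was called (adjusted p = 0.328 and 0.242). Both were called in camera with no filter on dim genes (0.025 and 0.01). There the lists were also set against the dim genes, whose median difference was -0.19 in CD49b+ and -0.199 in CD25+ cells. These calls may therefore reflect the lower dim genes.

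H2-Aa and Cd74 of the MHC class II pathway were lower in CD4+ cells of injected than of naive mice, though the call of H2-Aa was lost without any 1 array and that of Cd74 without 3 of the 4 (adjusted p up to 0.208). B cells among the cells of naive mice are argued against by Ighm, Cd79a and Cd79b, the highest of which lay at 4.67, under the array median of 4.79, although 3 of the 15 B cell markers measured apart from MHC class II genes and Cd74 lay above it and 2 of them fell. Monocytes or macrophages are argued against by Lyz2, C1qa, C1qb and C1qc, the highest at 4.23, although Adgre1 (6.12) and Cybb (7.19), also genes of these cells, lay above the median and fell. Dendritic cells stay open: 11 of 18 tested members of the myeloid and dendritic cell list fell by over 2 SE, Itgax among them, and a few such cells may have passed the negative selection and the sort on CD4, which would remove those without CD4. Other members of the list did not fall, among them Zbtb46 (0.03 ± 0.10) and Clec4a2 (-0.05 ± 0.13), and Xcr1 (4.21) lay under the median. Of the 29 members of that list 4 are in another list, H2-Aa stood at 10.73 in CD25+ cells with Itgax at 5.24, and an effect of the injections on the T cells themselves was not tested.

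In the same comparison 4 of 10 T follicular helper genes were called lower, a list call lost with an estimated correlation (adjusted p = 0.0701), and the calls of Bcl6 and Il21 were lost without 4 and 3 of the 4 arrays in turn. A smaller share of follicular helper and effector or memory cells may account for it: the effector and memory list had a median of -0.515, with 19 of 24 members lower by over 1 SE, but of the naive and quiescent list, with a median of 0.176, only 6 of 13 were higher by over 1 SE. A change of share and a change within cells cannot be told apart, since the arrays measure pooled cells.

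Foxp3 and Il2ra in CD49b+ cells lay between CD4+ and CD25+ cells. CD25+ cells like those of the CD25+ arrays within the CD49b+ sort would have to make up 22.3% of it to give the Foxp3 level. Of the 55 genes high in CD25+ cells, 8, Il2ra among them, lay too low for that share. With no minimum level 15 of 145 did, and 8 of the 130 above the array medians in CD49b+ cells. This argues against such a mixture as the whole source of Foxp3, though the needed share was taken without its error. For Il2ra, which needs 13.7%, 2 of 55, Cd83 and Sdc4, lay too low (at most 13% and 13.1%). With no minimum level 5 of 145 did, among them Plagl1, Bmp2 and Kcnk1 (at most 8.2%, 10.2% and 10.3%). Those of Plagl1, Bmp2 and Kcnk1 lay under the array medians in CD49b+ cells and may be near background. Cd83 and Sdc4 lay close to the needed share, which was taken without its error. This test therefore cannot tell whether such CD25+ cells were the source of Il2ra. An expression of Foxp3 by CD49b+ cells themselves was not tested.

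The genes left out as dim had a median difference from CD4+ cells of -0.19 in CD49b+ and -0.199 in CD25+ cells, and the nonspecific control probe sets one of -0.112 and -0.145. Of the 10 splits of the 6 CD49b+ and CD25+ arrays into 3 and 3, 1, the real one, gave as many as 3297 genes, and the highest of the others gave 0. With 10 splits no share under 0.05 can be reached, and only 4 of them part all 3 same-numbered pairs.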
